A study of Arabidopsis thaliana with 12 samples.

How the data were processed

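Small RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana, Col-0 and dcl4-2, on MS and MS-N medium, with 3 libraries in each of 4 groups. Per the submitters' processing notes, reads were aligned with Bowtie 1.2.2 and handled with SAMtools 1.9 on the build TAIR10, and neither the counting rule nor the test was stated. The deposited data are a table of 21-nt reads and a table of 22-nt reads over 32420 gene loci, and a table of 14 feature classes at both lengths. Raw reads were not analysed here. The deposited gene tables hold a signal per locus and group, which the header calls TPM. From the values, this signal is the mean over the 3 libraries of a group of whole reads divided by a size factor near 1, and it is called normalized reads in the text. The authors' log2 ratios were deposited for 4 comparisons of group pairs, and the authors' p-value and adjusted p-value columns stand beside them. The class table of the authors holds rpm, reads scaled to library size, of each library, and its header also says TPM.

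The gene tables give no value for single libraries, so these were recovered from the group means. Each mean is a sum of 3 whole numbers, each times a fixed step for its library. The steps were read from the lowest values, and every other mean was then split into the only combination of whole numbers that reproduces it. This recovered between 99.9% and 100% of the loci above 0 per group and length, with a largest remainder of 1.46e-11. A mean was tried only where chance combinations were unlikely. That no tried mean had more than 1 combination is therefore largely set by this rule. The loci left out are few but abundant. At 21 nt the means not split in a group hold 56.8, 79.7, 76.0 and 87.4% of the column sums of Col-0 on MS, Col-0 on MS-N, dcl4-2 on MS and dcl4-2 on MS-N, and at 22 nt 0, 20.6, 19.8 and 32.8%. A locus whose mean was not split in any 1 group was left out of all groups. The loci left out therefore hold at least these shares. All SDs, n and tests at loci rest on this recovery, since the deposited columns are means without a spread. Tested on simulated data drawn around the recovered reads of Col-0 on MS, the method split 18722 and 18768 means correctly and 0 wrongly. Abundant loci that were left out had no counterpart in this simulation. The 29 loci at 21 nt and 7 at 22 nt with no recovered value in at least 1 group are given as the authors' means with no SD and were left out of the tests. Recovered libraries carry no replicate number, so library 1, 2 and 3 of a group name the order of their size factors, largest first. No paired analysis was possible because of this, and libraries could not be matched between the 21-nt and the 22-nt table.

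In the class table every value of a library is a whole multiple of 1 step, which gave whole reads and library totals of 4515437 to 7270637, with at least 183 reads behind each value. The tasiRNA class overlaps the exon class, so totals were summed over the other 13 classes. Same-numbered libraries of different groups were checked for a shared preparation, and their correlations over 18 pairs ran from -0.519 to 0.779, so the libraries were not treated as paired. Class values were compared by two-sided exact permutation tests, with genotype permuted within medium or medium within genotype (400 arrangements), and adjusted over the 28 class values by Benjamini-Hochberg.

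Loci were compared with limma 3.58.1 in R 4.3.3, on log2(value + 1), with a mean-variance trend and 1 fit over the 4 groups, after a filter for a value of at least 1 in at least 3 of the 12 libraries. Benjamini-Hochberg adjustment ran over all loci kept, and an adjusted p of 0.05 was the threshold. A log2 change on this scale understates the change of loci with few reads, and folds in the text are ratios of group means. A fold against a group with 0 reads was computed against a floor of 3 reads over the group and is written as at least that fold, and with 1 to 3 reads the ratio has a 95% counting interval. Intervals and floors cover counting error only. Shares of 22-nt reads carry exact Clopper-Pearson intervals. The contrasts were medium in each genotype, genotype on each medium and the interaction, and these choices, the gene lists and the alternatives were fixed before the data were examined, apart from those named as chosen later. Of the locus identifiers 31710 matched a name in the RefSeq annotation of TAIR10.1, 26700 of them protein coding and 178 microRNA genes. No coordinates were used.

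Gene lists came from background knowledge: secondary siRNA sources, microRNA genes, microRNA families low or high under nitrogen limitation, families known for 22-nt microRNAs, nitrogen, photosynthesis, anthocyanin and RNA silencing genes, chloroplast and mitochondrial genes, and 4 loci the study is known for. The lists of tasiRNA precursors, of rRNA and tRNA genes and of transposons had 0 members in the gene tables and gave no result. The rRNA, tRNA and transposon lists were drawn by annotated biotype or identifier, so a transposon gene annotated under another biotype was not found by them. A list of annotated pseudogenes was added after the data were seen. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The rule for named genes took, for each comparison and length, among called loci whose groups do not overlap, the 8 largest log2 rises and 8 largest falls, the 5 largest rises and 5 largest falls in normalized reads, and members of the lists as examples. Which list members are named, and which loci of the rule the text describes, was chosen after their values were seen. Separation of the groups was not asked of the interaction.

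Each count was run again with pseudocounts of 0.1 and 5, without the filter and with a minimum of 5, with 3 other scalings and with scaling to rpm, without the trend, with only the compared groups in the fit, and without each library. A quasi-likelihood count test was planned in place of limma if the files held counts. The gene tables hold group means that are not whole multiples of 1 step, so it was not used here. The recovered reads would have allowed it. On simulated data limma recovered 22 of 67 changes of 2-fold, 58 of 67 of 4-fold and 63 of 66 of 8-fold at 21 nt. It made 2 false calls in 19190 loci. At 22 nt it recovered 19, 58 and 62, with 1 false call in 19953. All loci and groups were drawn with 1 spread, the median over loci with more reads in Col-0 on MS. Changes were placed only at loci with a mean of at least 5. These rates therefore do not describe changes at loci with fewer reads, or groups with a wider spread. A first version of this simulation drew all groups around the means of Col-0 on MS, where many loci have 0 reads, and made more false calls than the threshold allows. It was replaced by means over all 12 libraries, so the error rate at loci with 0 reads in whole groups is less certain. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.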

Results

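Small RNA was sequenced from whole Arabidopsis thaliana seedlings, 10 days old, on MS medium or on MS without nitrogen (MS-N). The seedlings were wild type Col-0 or dcl4-2, a mutant of DICER-LIKE 4 (DCL4), the enzyme that cuts long double-stranded RNA into 21-nt siRNAs. Each of the 4 combinations of genotype and medium had 3 biological replicates, which made 12 libraries of 4515437 to 7270637 reads. Reads of 21 nt and of 22 nt were available for 14 feature classes per library, as rpm, and for 32420 gene loci as group means of normalized reads. Values are means ± SD with n = 3 libraries throughout. A read count at a locus is the amount of small RNA from it, not the amount of its messenger RNA. The comparison of dcl4-2 with Col-0 asks which RNAs give 22-nt siRNAs when DCL4 is missing. That of MS-N with MS asks how nitrogen deprivation alters both size classes.

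DCL4 itself gave few small RNAs in every group. At 22 nt the locus held 4.56 ± 0.595 normalized reads in Col-0 on MS, 5.05 ± 2.19 in Col-0 on MS-N, 1.04 ± 0.0263 in dcl4-2 on MS and 7.17 ± 3.48 in dcl4-2 on MS-N. The 22-nt reads of DCL4 rose on MS-N in dcl4-2 (6.88-fold, 95% counting interval 1.92 to 35.4, log2 1.92, adjusted p = 0.00729, limma with Benjamini-Hochberg). Between genotypes DCL4 did not pass at 22 nt, with log2 -1.44 on MS (adjusted p = 0.209) and 0.41 on MS-N (adjusted p = 0.677). At 21 nt DCL4 held 2.92 ± 1.95 and 3.16 ± 1.96 normalized reads in Col-0 on MS and MS-N, and 1.11 ± 0.0497 and 2.31 ± 1.81 in dcl4-2. No 21-nt comparison of DCL4 passed. The 22-nt call of DCL4 ended with microRNA reads scaled to a common sum, with only the dcl4-2 libraries in the fit, and without library 3 of dcl4-2 on MS-N.

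Trans-acting siRNAs (tasiRNAs), products of DCL4 that silence other messenger RNAs, fell at 21 nt and rose at 22 nt in dcl4-2. On MS the 21-nt tasiRNAs held 26379 ± 3899.6 rpm in Col-0 and 1128 ± 147 in dcl4-2 (23.4-fold lower). On MS-N they held 45790.4 ± 4749 and 2675 ± 175 (17.1-fold lower). The 22-nt tasiRNAs went from 1021 ± 141 to 5632 ± 97.4 on MS and from 2859 ± 118 to 12530.4 ± 595 on MS-N, 5.52-fold and 4.38-fold higher. The 22-nt share of tasiRNA reads thus went from 3.73% to 83.3% on MS and from 5.90% to 82.4% on MS-N. Exon reads, a class that overlaps the tasiRNAs, fell at 21 nt from 35236 ± 4157 to 5806 ± 322 on MS and from 54680.4 ± 5017 to 12486 ± 638 on MS-N. At 22 nt they rose from 8479 ± 347 to 11018 ± 423 on MS, by 2539 rpm where the tasiRNAs rose by 4611. On MS-N they rose from 9898 ± 219 to 26356 ± 878, where the tasiRNAs went from 2859 to 12530.4. The deposited 22-nt mean of a single gene, the nitrate reductase NIA2, went from 108 to 45734 normalized reads on MS-N. Its part in the exon rise was not computed, so this rise does not show a broad gain over exons. MicroRNA reads, which DCL1 makes, rose in dcl4-2 at 21 nt (1.3-fold on MS, 1.45-fold on MS-N) and at 22 nt (1.22-fold and 1.38-fold). Promoter and intron reads fell at both sizes, 22-nt promoter reads from 8825 to 6261 on MS and from 13169.5 to 8664 on MS-N. The 22-nt reads of transposable elements, a source of heterochromatic siRNAs, also fell over both media, from 28746 ± 2226 to 17543 ± 576 on MS-N. On MS they were 18311 ± 2596 and 16402 ± 3399, and the groups overlapped (exact two-sided permutation p = 0.5), and with replicate number as a block this class did not pass (sign-flip p = 0.0938).

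In all, 15 of the 28 class values differed by genotype in a two-sided exact permutation test within media. The tasiRNA, exon and microRNA classes had p = 0.005 in this permutation test, the smallest this design gives, and adjusted p = 0.0127. Total 21-nt reads did not pass (exact two-sided permutation p = 0.465), at 177337 ± 13686 and 163033 ± 11008 rpm on MS. Without microRNA they fell (1.79-fold on MS and 1.5-fold on MS-N, p = 0.005 in the same permutation test). Total 22-nt reads rose over both media (permutation p = 0.01), from 113673 ± 2190.4 to 130538 ± 1401 on MS-N. On MS they were 86349 ± 5398 in Col-0 and 104747 ± 15826 in dcl4-2, where the groups overlapped (exact two-sided permutation p = 0.2). Replicate 1 of dcl4-2 on MS held 87521 rpm of 22 nt, within the Col-0 libraries, and replicates 2 and 3 held 118644 and 108075. The MS difference of 18398 rpm lay with 22-nt intergenic reads, which differed by 19688 rpm and of the MS libraries were high in these 2 alone. The 22-nt share of all 21- and 22-nt reads went from 32.8 ± 0.524% to 39.0 ± 4.86% on MS, and over both media it passed (permutation p = 0.04) but not with replicate number as a block (sign-flip p = 0.0938). On MS-N it was 30.9 ± 0.696% and 31.5 ± 0.681%, and the groups overlapped (exact two-sided permutation p = 0.5). Without microRNA the share was 45.6% and 64.1% on MS and 47.7% and 60.4% on MS-N (permutation p = 0.005 over both media). Within a single medium the smallest exact p is 0.1. With replicate number as a block none of the 28 class values passed after adjustment. In this exact two-sided sign-flip test over 6 pairs 11 of the 15 had the smallest possible p of 0.0312 (adjusted p = 0.0795), and 4 had p of 0.0625 to 0.0938.

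**Figure D1:**
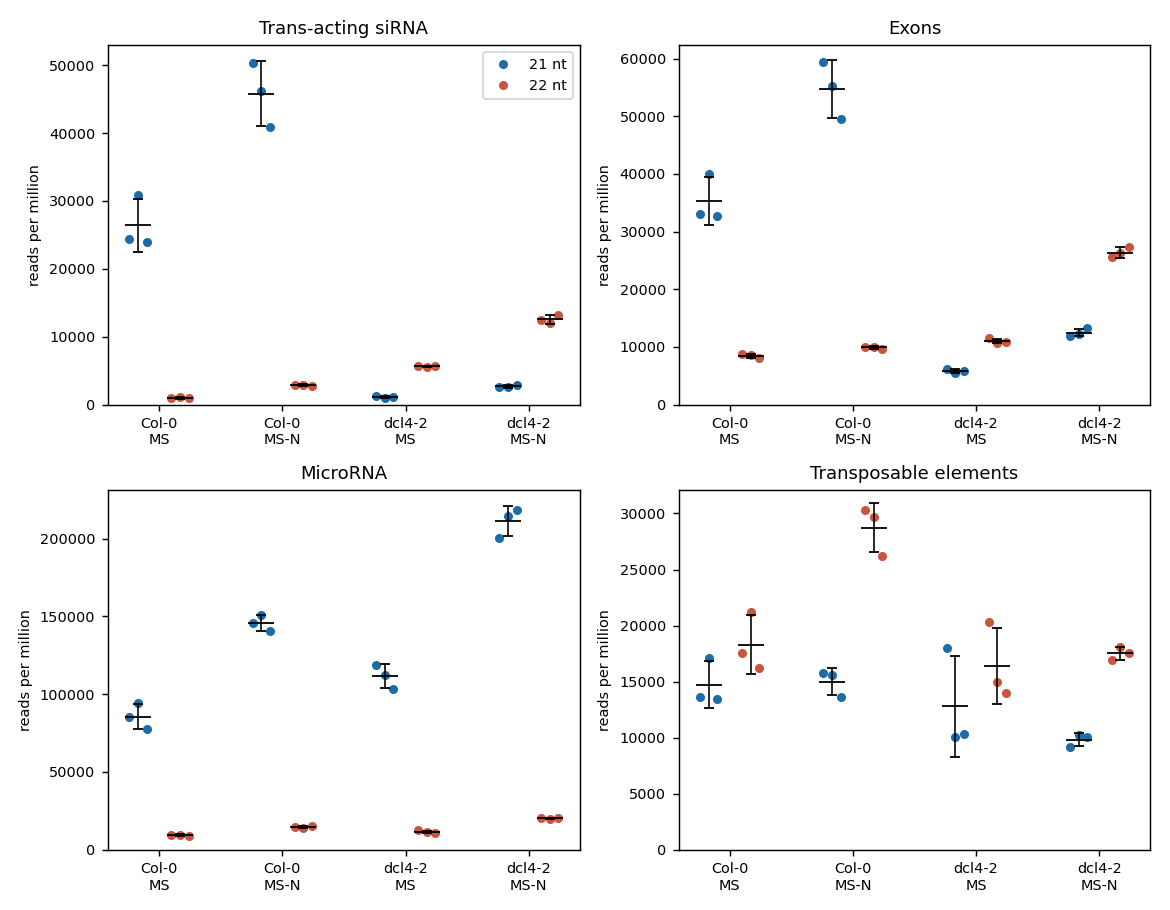
Values in rpm (linear axis) of 4 feature classes in the 12 libraries, with 21-nt reads in blue and 22-nt reads in red, a point for each library, a bar for the mean and a whisker for 1 SD. The 21-nt tasiRNAs averaged 26379 in Col-0 and 1128 in dcl4-2 on MS, and the 22-nt tasiRNAs 1021 and 5632.

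On MS-N most classes held more small RNA in rpm in both genotypes. MicroRNA reads of 21 nt rose from 85653 ± 8204 to 145602 ± 5189 in Col-0 and from 111687 ± 7732 to 211199 ± 9553 in dcl4-2. The 21-nt tasiRNAs rose 1.74-fold in Col-0 and 2.37-fold in dcl4-2, and the 22-nt tasiRNAs 2.80-fold and 2.22-fold. Small nucleolar RNAs, guides of ribosomal RNA modification, rose at 21 nt from 249 ± 28.5 to 608 ± 40.7 in Col-0 and from 227 ± 49.9 to 1042 ± 61.2 in dcl4-2. Small nuclear RNAs rose at both sizes. Pseudogene reads fell at both sizes, with overlap of the groups in Col-0 at 21 nt, and at 22 nt from 697 ± 32.9 to 567 ± 21 in Col-0 and from 627 ± 37.0 to 544 ± 26.5 in dcl4-2. The 22-nt reads of transposable elements were 1.57-fold higher in Col-0, while in dcl4-2 the groups overlapped (1.07-fold, exact two-sided permutation p = 0.6), and with replicate number as a block this class did not pass (sign-flip p = 0.0938). Across genotypes 21 of 28 class values passed the two-sided exact permutation test, those of microRNA, tasiRNA and small nucleolar RNA at adjusted p = 0.00778. Of the 28 values 20 passed with replicate number as a block. Total reads rose at 21 nt (1.43-fold and 1.74-fold) and at 22 nt (1.32-fold and 1.25-fold), both with permutation p = 0.005. The 22-nt share of all reads fell by 1.85 points in Col-0 and by 7.51 in dcl4-2 (permutation p = 0.005). In dcl4-2 the share on MS varied (39.0 ± 4.86%), and leaving out 1 library gave differences of -10.3 to -5.95 points. Without microRNA the share did not fall in Col-0, at 45.6% on MS and 47.7% on MS-N. In dcl4-2 it was then 64.1 ± 5.74% and 60.4 ± 1.02%, and over both genotypes the medium effect did not pass (permutation p = 0.575).

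On MS, the loci whose 21-nt siRNAs fell in dcl4-2 included pentatricopeptide repeat (PPR) genes, a family with messengers cut by miR161 and tasiRNAs. AT1G62910 went from 2222 ± 215 to 10.2 ± 9.23 normalized reads (218-fold lower). RPF3 (AT1G62930), which processes mitochondrial transcripts, went from 2013 ± 218 to 16.2 ± 9.40 (124-fold lower). RPF2 (AT1G62670) fell 168-fold. At 22 nt AT1G62910 fell 6.19-fold and AT1G63400, another PPR gene, 13.6-fold. Other loci gained 22-nt reads. MYB28, a regulator of glucosinolate genes, rose from 3.40 ± 2.71 to 307 ± 139 (90.3-fold). SMXL4 (AT4G29920), which acts in phloem formation, rose from 1.32 ± 0.627 to 182 ± 107 (138-fold). PHB, a leaf polarity factor and target of miR165 and miR166, rose 40.9-fold. NIA1, a nitrate reductase gene, held 38.0 ± 14.9 and 1166 ± 951 reads of 22 nt (30.6-fold higher).

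Of 41 measured genes that are known to give secondary siRNAs or to be cut by their triggers, 22 fell at 21 nt, 1 rose and 18 did not pass on MS (23 and 1 adjusted over the list alone, median log2 -1.60). At 22 nt 7 of these rose, among them AGO1, an effector of microRNAs, (2.79-fold) and ARF4, an auxin response factor and tasiRNA target, (7.69-fold). In the same list 12 fell and 22 did not pass (11 and 13 adjusted over the list alone, median 0.34). The camera direction was nevertheless down, with camera adjusted p = 0.0153 at the preset correlation and 0.163 with an estimated one. The fry direction was also down (fry adjusted p = 0.0310). Of 125 microRNA genes 44 rose at 21 nt, 1 fell and 80 did not pass (58 and 2 adjusted over the list alone). With microRNA reads scaled to a common sum this became 15 rises and 14 falls. The deposited 21-nt means of MIR157a and MIR157b were both 7462.12 in dcl4-2 on MS. Members of a family may thus share reads, and no count of microRNA genes here or below is a count of independent genes. MIR390a, whose product triggers the ARF-targeting tasiRNAs, held 971 ± 71.3 and 3487 ± 1273 reads of 21 nt (3.59-fold higher). At 22 nt 20 of 139 microRNA genes rose, 3 fell and 116 did not pass (40 and 7 adjusted over the list alone). With that scaling 2 rose and 11 fell. Of 3 measured loci for which the study is known as 22-nt sources (NIA1, SMXL4 and SMXL5 (AT5G57130)), 2 rose at 22 nt and 1 did not pass (2 adjusted over the list alone), which is not independent evidence because the list comes from the study.

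limma with Benjamini-Hochberg called 252 of 19390 loci at 21 nt on MS (100 higher and 152 lower in dcl4-2, 149 of them protein coding and 45 microRNA genes) and 296 of 20153 at 22 nt (179 higher and 117 lower). The groups did not overlap at 12.1% of loci at 21 nt and 11.9% at 22 nt, where chance gives 10% for values without ties. With ties, as at loci with 0 reads in several libraries, the chance level is lower. With only the 6 libraries on MS in the fit 26 and 23 loci passed. The 22-nt calls of NIA1, ARF4 and AGO1 and the 21-nt call of MIR390a ended in that fit. Without a variance trend 87 and 78 passed, with a pseudocount of 0.1 the 22-nt count was 183, and with microRNA reads scaled to a common sum 1787 and 899, of which 1745 and 794 were lower.

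On MS-N, NIA2, the major nitrate reductase gene, averaged 108 reads of 22 nt in Col-0 and 45734 in dcl4-2 in the authors' deposited table (deposited log2 ratio 8.72, deposited adjusted p = 1.00e-56). Of the loci tested here SMXL4 (AT4G29920) had the largest 22-nt rise in log2 terms, from 2.32 ± 2.2 to 626 ± 347 normalized reads (269-fold), and its 21-nt reads rose 32.3-fold. NF-YA2, a transcription factor gene targeted by miR169, rose at 22 nt from 1.19 ± 0.440 to 68.5 ± 11.3 (57.4-fold). At 22 nt PHB rose 30.7-fold, APR1, an enzyme of sulfate reduction, 26.2-fold, and MYB28 18.5-fold. NIA1 rose from 75.5 ± 27.1 to 597 ± 144 (7.91-fold), and the effector genes AGO2 (15.5-fold) and AGO1 (3.53-fold) rose as well. The 21-nt siRNAs of PPR genes named for MS fell on this medium too, AT1G62910 98.6-fold, RPF2 115-fold and RPF3 93.9-fold. Chloroplast genes, fragments of whose abundant transcripts enter small RNA libraries, held more 22-nt reads in dcl4-2. In the limma test 71 of 88 were higher, 0 lower and 17 not past it (81 higher adjusted over the list alone, median log2 1.36, adjusted p = 1.16e-04 with an estimated correlation). Reads of tRNA, a sign of RNA fragments, moved with them, at 2732 ± 356 rpm at 22 nt in Col-0 and 4453 ± 229 in dcl4-2 on MS-N.

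Of the 41 secondary siRNA sources 21 fell at 21 nt on MS-N, 1 rose and 19 did not pass (23 and 2 adjusted over the list alone). At 22 nt 11 of them rose, 11 fell and 19 did not pass (18 and 13, adjusted over the list alone, median 0.94). The camera direction was down, with camera adjusted p = 0.186 at the preset correlation and 0.395 with an estimated one. The fry direction was up (fry adjusted p = 0.128). MicroRNA genes rose at 21 nt in 52 of 125 cases, 1 fell and 72 did not pass (73 higher adjusted over the list alone). With microRNA reads scaled to a common sum 7 rose and 7 fell. At 22 nt 47 of 139 rose and 4 fell (61 and 4 adjusted over the list alone), which turned to 3 and 8 with that scaling. Of 118 mitochondrial genes 34 rose at 22 nt, 1 fell and 83 did not pass (44 and 3 adjusted over the list alone). Of 20 nuclear photosynthesis genes 7 rose and 13 did not pass (9 adjusted over the list alone, adjusted p = 0.145 with an estimated correlation). Nitrogen genes rose in 7 of 28 cases at 22 nt with 21 not past the test (8 adjusted over the list alone), among them the cytosolic glutamine synthetase GSR 1 (3.26-fold, a call that ended without library 2 of Col-0 on MS-N and in 3 other settings). RNA silencing genes rose in 4 of 15 with 11 not past (6 adjusted over the list alone). Anthocyanin genes rose in 3 of 9 cases with 6 not past (4 adjusted over the list alone). Chloroplast genes at 21 nt fell in 18, rose in 6 and did not pass in 64 (31 and 10 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation). Reads of abundant RNA stood higher in dcl4-2 on MS-N with no overlap of the groups, at 22 nt 1.63-fold for tRNA, 1.66-fold for rRNA and 1.70-fold for small nucleolar RNA. All 3 measured loci the study is known for rose at 22 nt (3 adjusted over the list alone, not independent evidence).

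limma with Benjamini-Hochberg called 893 of 19390 loci at 21 nt (454 higher, 439 lower) and 1273 of 20153 at 22 nt (845 higher, 428 lower). The groups did not overlap at 23.8% and 25.8% of loci, against 10% by chance for values without ties. Without a variance trend 375 and 339 passed, with only the libraries on MS-N in the fit 349 and 522, and with a pseudocount of 0.1 447 and 795. With microRNA reads scaled to a common sum 1688 and 1963 passed, 1635 and 1798 of them lower. Trimmed-mean scaling turned the 22-nt balance to 518 higher and 792 lower. The 21-nt count was 422, 422 and 443 without library 1, 2 or 3 of Col-0 on MS-N and 587 and 507 without library 2 or 3 of dcl4-2 on MS-N. The 22-nt count was 645, 532 and 728 without a Col-0 library and 786 without library 2 of dcl4-2.

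The PPR genes AT1G62910, RPF2 and RPF3 were among 97 loci lower at 21 nt in dcl4-2 on both media, where independent lists of these sizes would share 3.44. A further 42 loci were higher at 21 nt on both media (2.34 for independent lists). At 22 nt 75 loci were higher on both media, MYB28, PHB and SMXL4 (AT4G29920) among them, and 71 were lower (7.51 and 2.48 for independent lists). Across genes, which are not independent replicates, the genotype effects on MS and MS-N had Pearson r = 0.138 and Spearman rho = 0.0185 at 21 nt, and 0.0508 and -0.0309 at 22 nt.

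**Figure D2:**
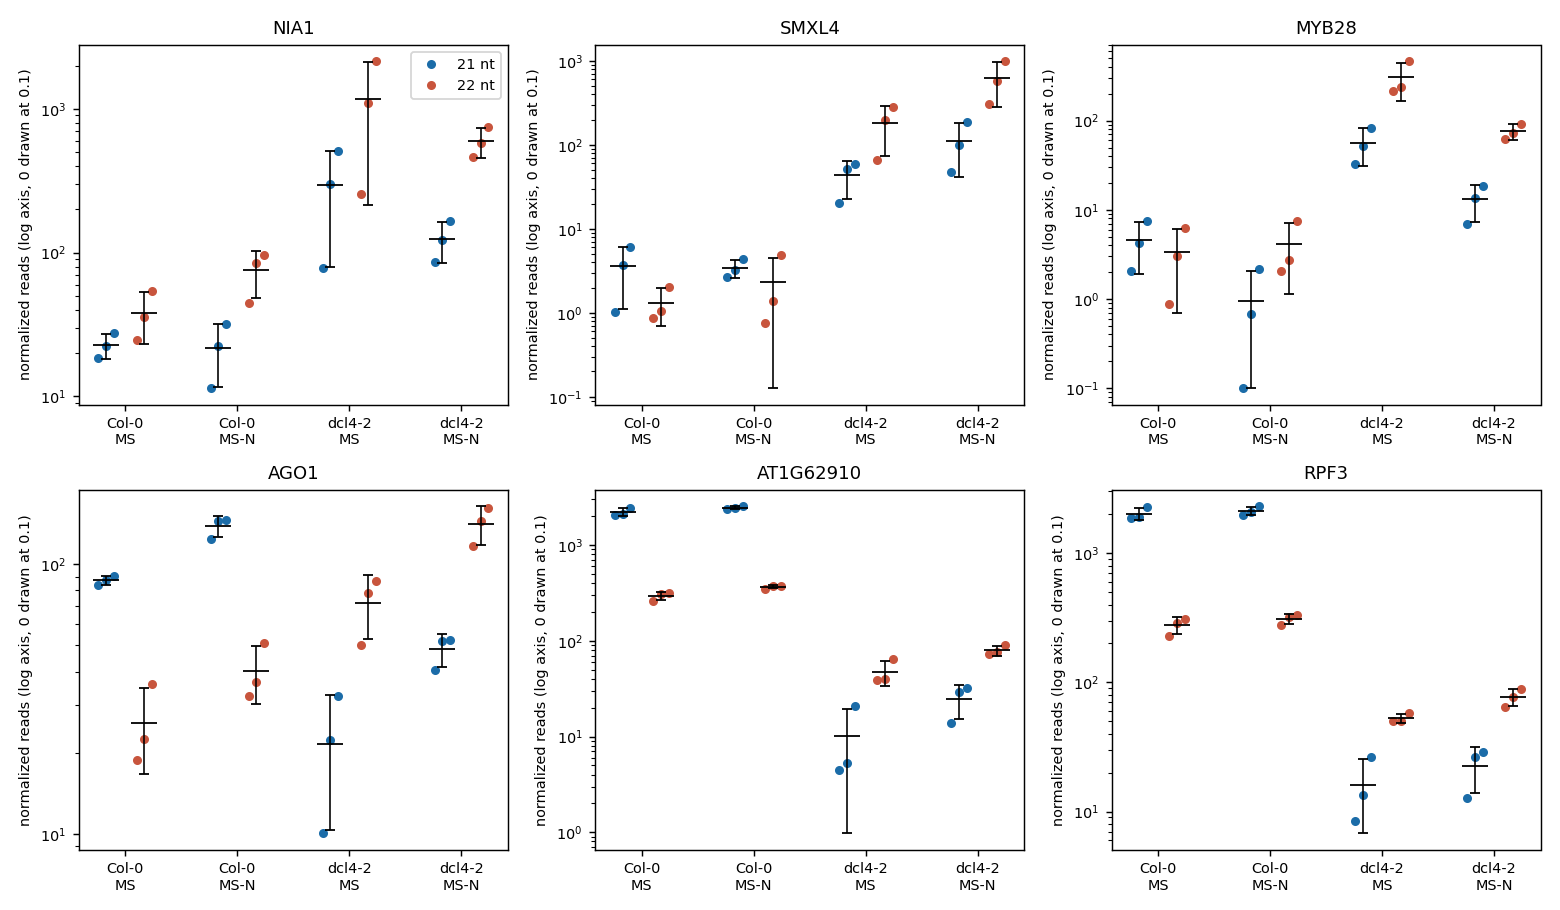
Normalized reads (log axis, 0 drawn at 0.1) at NIA1, SMXL4, MYB28, AGO1, AT1G62910 and RPF3 in the 12 libraries, with 21-nt reads in blue and 22-nt reads in red, a point for each library and a bar for the mean. SMXL4 (AT4G29920) averaged 1.32 reads of 22 nt in Col-0 and 182 in dcl4-2 on MS, and AT1G62910 2222 and 10.2 reads of 21 nt.

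In Col-0, MIR399b, MIR399a and MIR395b, known from phosphate and sulfate starvation, were among the microRNA genes that fell on MS-N. MIR399b, whose product targets the phosphate regulator PHO2, went from 742 ± 172 to 3.42 ± 1.24 normalized reads of 21 nt (217-fold lower), MIR395b, which targets ATP sulfurylases, fell 56.7-fold. MIR399a fell at 22 nt from 2873 ± 580.2 to 10.4 ± 7.80 (275-fold). MIR169f, whose family is listed among those known to be low under nitrogen limitation, instead rose at 21 nt from 184 ± 25.9 to 1368 ± 117 (7.44-fold). Reads of the high-affinity nitrate transporter NRT2:1 rose at 21 nt from 0 to 17.5 ± 6.43 (at least 18.6-fold), those of PAP1, an activator of anthocyanin synthesis, 28.7-fold, and those of the amino acid permease AAP2 27.1-fold. LHB1B1, a light-harvesting chlorophyll-binding protein, fell from 148 ± 18.5 to 1.57 ± 1.01 at 21 nt (93.8-fold) and 161-fold at 22 nt. The Rubisco subunits RBCS3B (nuclear) and rbcL (ATCG00490) fell 91.8-fold and 11.5-fold at 22 nt.

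All 20 nuclear photosynthesis genes fell on MS-N in Col-0 at 21 nt and at 22 nt (median log2 -4.71 and -5.29, 20 and 20 adjusted over the list alone). Of 88 chloroplast genes 51 fell at 21 nt and 74 at 22 nt, with 0 higher at either size and 37 and 14 not past the limma test (60 and 81 adjusted over the list alone). In the same libraries 22-nt reads of tRNA fell from 4822.5 ± 140 to 2732 ± 356 rpm and those of rRNA from 2007 ± 308 to 1454 ± 55.8. Those of small nucleolar RNA rose from 226 ± 15.2 to 529 ± 31.6. The microRNA families known to be low under nitrogen limitation fell in 17 of 30 members at 21 nt, rose in 4 and did not pass in 9 (18 and 4 adjusted over the list alone). At 22 nt 14 of 33 fell, 1 rose and 18 did not pass (19 and 1 adjusted over the list alone). Those known to be high rose in 3 of 4 at 21 nt, MIR842 (6.06-fold) and MIR160c (3.80-fold) among them, and in 3 of 5 at 22 nt, MIR846 (5.31-fold) among them (4 and 5 adjusted over the list alone). Of 125 microRNA genes 36 rose and 34 fell at 21 nt (40 and 36 adjusted over the list alone), and 30 and 28 of 139 at 22 nt (33 and 35 adjusted over the list alone). This balance turned to 20 and 41, and 19 and 38, with microRNA reads scaled to a common sum.

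Nitrogen genes went both ways in Col-0, with 6 of 27 higher, 7 lower and 14 not past the test at 21 nt (9 and 10 adjusted over the list alone). At 22 nt 6 of 28 were higher, 7 lower and 15 not past (9 and 10 adjusted over the list alone). GSR 1 rose 9.62-fold at 21 nt and 17.3-fold at 22 nt. ASN1, an asparagine synthetase, fell from 120.3 ± 36.0 to 3.84 ± 1.29 at 21 nt. The plastid glutamine synthetase GS2 fell 11.5-fold and LBD39, a repressor of nitrate genes, fell at least 14.8-fold. Anthocyanin genes rose in 3 of 8 cases at 21 nt with 5 not past (4 adjusted over the list alone). At 22 nt limma with Benjamini-Hochberg called 0 of 9 of them singly and 2 adjusted over the list alone (adjusted p = 0.085 with an estimated correlation). Of 4 measured genes listed from background knowledge for 22-nt microRNAs MIR173, a trigger of tasiRNAs, rose at 22 nt (2.54-fold, a call that ended without a variance trend), and 3 did not pass (1 higher adjusted over the list alone). Reads of 22 nt were a minor part of MIR173, 0.779% of 28765 reads in Col-0 on MS (95% Clopper-Pearson interval 0.680 to 0.887%, reads pooled over 3 libraries). In the list of secondary siRNA sources 2 rose and 2 fell at 21 nt, and 1 and 1 at 22 nt.

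limma with Benjamini-Hochberg called 1156 of 19390 loci at 21 nt in Col-0 (405 higher and 751 lower on MS-N) and 1282 of 20153 at 22 nt (366 and 916). The groups did not overlap at 23.4% and 23.8% of loci, against 10% by chance for values without ties. At 21 nt 700 loci passed with a pseudocount of 0.1 and 2006 with microRNA reads scaled to a common sum, 1673 of them lower.

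In dcl4-2, glutamine synthetase GSR 1 gained small RNA on MS-N, from 2.62 ± 1.81 to 94.6 ± 10.3 normalized reads at 21 nt (36.1-fold) and from 0.7 ± 0.607 to 94.5 ± 2.82 at 22 nt (135-fold, 95% counting interval 37.2 to 1129). ICL, an enzyme of the glyoxylate cycle, rose at 21 nt from 0 to 46.7 ± 7.50 (at least 42.1-fold). Chalcone synthase TT4 rose at least 22.2-fold, the chaperone gene HSP70 24.8-fold and NRT2:1 at least 23.7-fold. AGO2 rose at 21 nt from 522 ± 149 to 1933 ± 47.1 (3.70-fold) and at 22 nt 3.75-fold. NF-YA2 rose at 22 nt 95.9-fold (95% counting interval 27.2 to 829), and the glucosyltransferase UGT71B5 at 22 nt 22.9-fold. MIR399b fell 120.0-fold and MIR395b 79.3-fold at 21 nt. ASN1 fell from 139 ± 43.8 to 1.85 ± 2.28 (75.3-fold), and the carbonic anhydrase CA1 fell at 22 nt from 39.0 ± 5.66 to 0 (at least 31.9-fold).

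All 20 photosynthesis genes fell on MS-N in dcl4-2 at both sizes (median log2 -3.93 at 21 nt and -3.85 at 22 nt, 20 and 20 adjusted over the list alone). Of 88 chloroplast genes 63 fell at 21 nt and 25 did not pass (68 adjusted over the list alone). At 22 nt 36 fell, 7 rose and 45 did not pass (40 and 7 adjusted over the list alone). The microRNA families known to be low under nitrogen limitation fell in 14 of 30 members at 21 nt and 13 of 33 at 22 nt, rose in 1 and 1, and did not pass in 15 and 19 (22 and 16 lower adjusted over the list alone). Those known to be high rose in 3 of 4 and 3 of 5 (3 and 5 adjusted over the list alone, adjusted p = 0.183 at 21 nt with an estimated correlation). Of the microRNA genes 40 rose and 33 fell at 21 nt, and 44 and 26 at 22 nt (44, 42, 49 and 31 adjusted over the list alone). This became 23 and 49, and 26 and 35, with microRNA reads scaled to a common sum. At 22 nt 2 of the 4 genes listed for 22-nt microRNAs rose, MIR173 (3.26-fold) and MIR828, a trigger of siRNAs from MYB genes (at least 5.93-fold), with 2 higher and 1 lower adjusted over the list alone.

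Nitrogen genes rose in 10 of 27 cases at 21 nt in dcl4-2 and fell in 5, and rose in 12 of 28 and fell in 7 at 22 nt (11 and 9, and 16 and 9, adjusted over the list alone). Scaling microRNA reads to a common sum turned the 21-nt balance to 7 and 9. The glutamine synthetase GLN1.3 rose 30.5-fold (95% counting interval 5.0 to 1237) at 21 nt and the ammonium transporter AMT1;3 at least 15.3-fold at 22 nt. The plastid glutamate synthase GLU1 fell 2.83-fold at 21 nt. Anthocyanin genes rose in 7 of 8 at 21 nt and 7 of 9 at 22 nt (7 and 9 adjusted over the list alone), DFR, a reductase of the pathway, among them (at least 9.63-fold at 21 nt). RNA silencing genes rose in 3 of 14 at 21 nt and 7 of 15 at 22 nt (5 and 7 adjusted over the list alone, adjusted p = 0.0727 at 21 nt with an estimated correlation). Secondary siRNA sources rose in 10 of 41 at 21 nt (adjusted p = 0.119 with an estimated correlation) and 10 at 22 nt, where 1 fell (adjusted p = 0.0906 with an estimated correlation), with 14 and 13 higher adjusted over the list alone. Their 22-nt median turned from 0.52 to -0.03 with microRNA reads scaled to a common sum. Mitochondrial genes rose in 22 of 116 at 21 nt and 29 of 118 at 22 nt, with 3 and 5 lower (23 and 33 higher adjusted over the list alone, adjusted p = 0.275 and 0.0906 with an estimated correlation). That scaling turned the 22-nt median from 0.41 to -0.04. In the same dcl4-2 libraries reads of abundant RNA, a sign of RNA fragments, stood higher on MS-N with no overlap of the groups, at 21 nt 1.47-fold for tRNA and 4.59-fold for small nucleolar RNA, and at 22 nt 1.14-fold for tRNA, 1.32-fold for rRNA and 4.72-fold for small nucleolar RNA. In Col-0 the 21-nt ratio was 0.616 for tRNA and 2.44 for small nucleolar RNA.

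limma with Benjamini-Hochberg called 2547 of 19390 loci at 21 nt in dcl4-2 (1644 higher, 903 lower) and 3153 of 20153 at 22 nt (1992 and 1161). The groups did not overlap at 23.7% and 28.5% of loci, against 10% by chance for values without ties. With only the dcl4-2 libraries in the fit 699 and 1244 passed. Loci called in both genotypes numbered 233 higher and 418 lower at 21 nt, MIR399b and LHB1B1 among the latter. At 22 nt they numbered 203 higher and 489 lower, NRT2:1 and GSR 1 among the former. Independent lists would share 34.3, 35.0, 36.2 and 52.8 loci, which is not a chance level for the reason given for the genotype lists. Across genes the medium effects in the 2 genotypes had Pearson r = 0.447 and Spearman rho = 0.290 at 21 nt, and 0.436 and 0.290 at 22 nt.

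**Figure D3:**
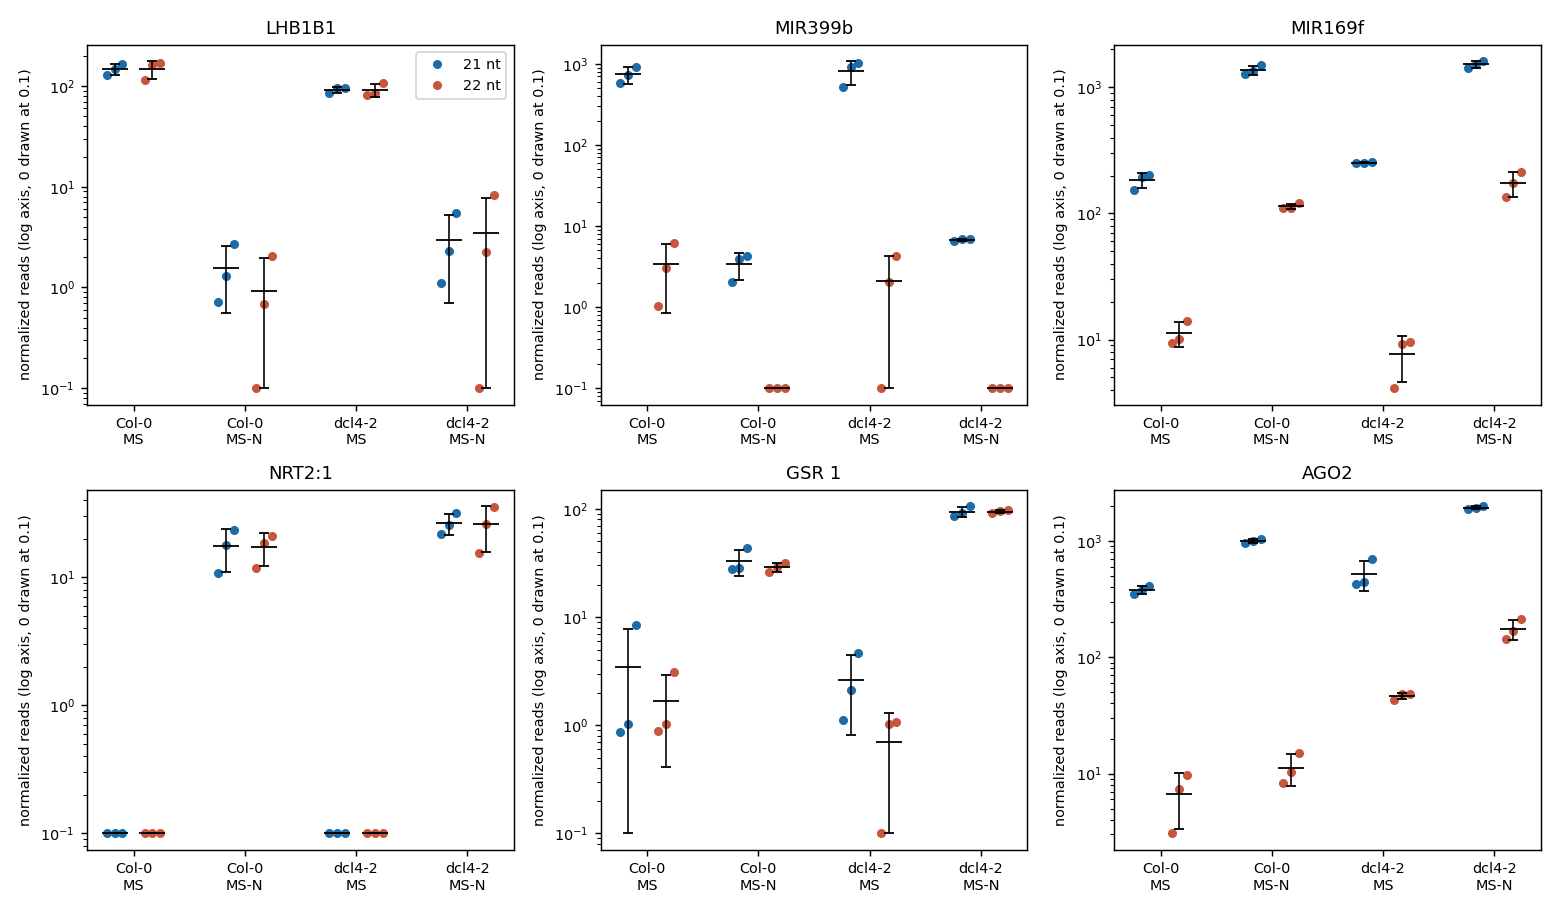
Normalized reads (log axis, 0 drawn at 0.1) at LHB1B1, MIR399b, MIR169f, NRT2:1, GSR 1 and AGO2 in the 12 libraries, with 21-nt reads in blue and 22-nt reads in red, a point for each library and a bar for the mean. MIR399b averaged 742 reads of 21 nt on MS and 3.42 on MS-N in Col-0, and GSR 1 2.62 and 94.6 in dcl4-2.

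The interaction of genotype and medium asks whether nitrogen deprivation acted differently in dcl4-2. Among the called loci with library values, which leave out NIA2, APR1 had the largest interaction at 22 nt (log2 4.95 ± 0.83 (SE), adjusted p = 2.57e-04, limma with Benjamini-Hochberg, 12 libraries), with 1.81 ± 2.29 and 2.32 ± 1.4 normalized reads in Col-0 on MS and MS-N and 0.357 ± 0.619 and 60.8 ± 33.3 in dcl4-2. AT3G04210 (log2 4.82 ± 0.86 (SE), adjusted p = 6.59e-04) and NF-YA2 (log2 4.44 ± 0.79 (SE), adjusted p = 6.63e-04) followed in the limma fit. MYB28 went the other way in limma (log2 -2.20 ± 0.53 (SE), adjusted p = 0.018). FDH, a formate dehydrogenase, had the lowest adjusted p of the named loci at 21 nt (log2 3.66 ± 0.69 (SE), adjusted p = 0.00578 in limma). Chloroplast genes kept more 22-nt reads on MS-N in dcl4-2. In limma 39 of 88 passed in that direction and 0 in the other (73 adjusted over the list alone, median log2 1.42, adjusted p = 3.72e-04 with an estimated correlation), psbA (ATCG00020) among them (log2 1.13 ± 0.17 (SE), adjusted p = 5.95e-05). Reads of 22 nt from tRNA and rRNA moved the same way, by 1.01 and 0.87 on the log2 scale. Photosynthesis genes passed in 8 of 20 cases (12 adjusted over the list alone, adjusted p = 0.0738 with an estimated correlation) and mitochondrial genes in 12 of 118 (18 adjusted over the list alone, adjusted p = 0.0738 with an estimated correlation).

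limma with Benjamini-Hochberg called 86 loci at 21 nt (74 higher and 12 lower in dcl4-2 relative to Col-0) and 412 at 22 nt (356 and 56). Without a variance trend limma called 0 at 21 nt, with 2645 loci at an unadjusted p under 0.05, and 2 at 22 nt. With a pseudocount of 0.1 the counts were 7 and 136, and the 21-nt count was 228 with a pseudocount of 5, 29 without a filter, 297 with a minimum of 5, 30 with trimmed-mean scaling and 148 in rpm. Of the loci named here AT3G04210 kept its call under every alternative, while NF-YA2 lost it with a pseudocount of 0.1 and APR1, MYB28, FDH and ATCG00020 without a variance trend. The 21-nt count was 41, 19 and 1 without library 1, 2 or 3 of Col-0 on MS, 7, 20 and 25 for Col-0 on MS-N, 37, 32 and 14 for dcl4-2 on MS-N and 211 without library 3 of dcl4-2 on MS. The 22-nt count was 169 and 192 without library 2 or 3 of Col-0 on MS, 198, 178 and 264 for Col-0 on MS-N, and 210 and 190 without library 2 or 3 of dcl4-2 on MS-N.

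At sources of secondary siRNA the share of 22-nt reads was higher in dcl4-2. At AGO1 it went from 22.5% in Col-0 on MS (95% Clopper-Pearson interval 18.3 to 27.2%, reads pooled over 3 libraries) to 78.1% in dcl4-2 (72.6 to 82.9%). At ARF4 it went from 10.7% (6.12 to 17.1%) to 76.0% (68.3 to 82.7%), and at RPF3 from 11.7% (11 to 12.5%) to 77.9% (71.5 to 83.6%). The auxin receptor genes AFB2 and AFB3 went from 19.4% to 73.1% and from 26.8% to 78.9%, and DCL1, the enzyme that makes microRNAs, from 30.3% to 81.1%. Of 1557 loci with at least 50 reads in every group, 35 gained more than 30 points on both media and 0 lost as much, with 27 protein-coding genes and 0 microRNA genes among the gains, in a count without a significance test. Of the 35 loci 18 were listed sources of secondary siRNA, among them AGO1, ARF4, RPF3 and AT1G62910. At AGO1 and ARF4 22-nt reads rose, while at RPF3 they numbered 859 in Col-0 and 152 in dcl4-2 on MS. Over the listed sources the pooled raw 22-nt reads went down from 10941 to 4612 on MS and from 14846 to 4696 on MS-N. Reads of both lengths were 64463, 6029, 87085 and 6536 in that order, so the pooled share was higher through the loss of 21-nt reads. Raw reads are not scaled for depth. On MS-N the 22-nt size factors were 1.33 to 1.45 in Col-0 and 0.72 to 0.90 in dcl4-2, so raw reads overstate the fall there. Single sources went both ways at 22 nt in limma, with 7 higher and 12 lower on MS and 11 and 11 on MS-N. Their median log2 change was 0.34 on MS and 0.94 on MS-N. Pooled over the listed sources the share was 17.0% and 17.0% in Col-0 on MS and MS-N and 76.5% and 71.8% in dcl4-2, against 35.6%, 29.8%, 26.7% and 29.3% over 151 microRNA genes. These leave out the most abundant ones, and over all microRNA reads of the class table the share was 9.95%, 9.20%, 9.34% and 8.78%. The median locus moved by 1.81 points on MS and 2.87 on MS-N.

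Library values could not be resolved in every group for 29 loci at 21 nt and 7 at 22 nt, most of them abundant microRNAs but also NIA2, and these are given only as the authors' means. The authors' means of NIA2 at 22 nt were 71.2 in Col-0 on MS, 108 in Col-0 on MS-N, 166 in dcl4-2 on MS and 45734 in dcl4-2 on MS-N, and at 21 nt they were 59.6, 71.3, 50.3 and 8383 (deposited log2 ratio 6.88 for genotype on MS-N). Among abundant microRNAs of the authors' deposited table, MIR398c, which targets copper proteins, had 21-nt means of 10386 on MS and 859 on MS-N in Col-0 and 13568 and 2159.8 in dcl4-2. MIR319b, which targets TCP genes, had 1269 and 7008 in Col-0 and 5027 and 14506 in dcl4-2, and MIR845a 3040.2, 3562, 4416 and 27893 in the same order. At an adjusted p of 0.05 the authors' columns called 828 and 1265 loci at 21 and 22 nt for medium in Col-0, 979 and 1815 for medium in dcl4-2, and 572 and 1220 for genotype on MS-N. Of these 785, 1136, 962, 1792, 488 and 990 were also called by limma, all with the same sign. Between dcl4-2 on MS-N and Col-0 on MS, which differ in genotype and medium together, the authors' columns called 1029 loci at 21 nt and 1627 at 22 nt.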

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

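All tests in this part were chosen after the results were seen, except the interaction fit itself. The effect of nitrogen deprivation differed between the genotypes at 86 loci at 21 nt and 412 at 22 nt in the interaction term of limma with Benjamini-Hochberg. Of 100 splits that reassign the medium within each genotype 11 gave as many loci at 21 nt and 5 at 22 nt, the real one included, so they do not exclude chance. They do not speak for it either, since such a split moves the medium effect that both genotypes share into the contrast. The highest other splits, with 2726 and 3200 loci, were those with the media swapped in 1 genotype and show this effect, and without them the highest called 517 and 476. When instead the residuals of genotype plus medium were shuffled over the libraries, 1 of 100 orders gave as many at either length, the real one, with 63 and 10 loci in the highest other. For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 1156 and 0 for medium in Col-0 at 21 nt, 1282 and 0 at 22 nt, 2547 and 1 for medium in dcl4-2 at 21 nt, 3153 and 5 at 22 nt, 252 and 7 for genotype on MS at 21 nt, 296 and 4 at 22 nt, 893 and 0 for genotype on MS-N at 21 nt, and 1273 and 2 at 22 nt.

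Named loci whose medium effect differed between genotypes at 22 nt were APR1 (log2 4.95), AT3G04210 (4.82), NF-YA2 (4.44), ATCG00020 (1.13) and MIR162b (0.64), which were higher in dcl4-2 on MS-N than the other groups foretell. AT1G69160 (log2 -3.38), AT5G33254 (-3.27), MYB28 (-2.20) and AT2G02840 (-1.10) were lower. At 21 nt REF6 (log2 3.72), FDH (3.66), AT3G24190 (3.65), AT5G43740 (1.48) and AT2G35750 (1.22) were higher. MIR836 (log2 -3.64), AT5G29408 (-3.51), AT1G03940 (-3.03) and MIR156f (-1.38) were lower. The normalized reads behind AT3G04210 were 3.33, 0.482, 0 and 8.89 in Col-0 on MS, Col-0 on MS-N, dcl4-2 on MS and dcl4-2 on MS-N, and those behind REF6 were 2.41, 0.218, 0 and 4.77. The median interaction over annotated pseudogenes was -0.59 at 21 nt and -0.54 at 22 nt, and over chloroplast genes 1.42 at 22 nt.

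Some class values moved in opposite directions in 2 comparisons, with no overlap between the libraries of the groups in either, and these differences between effects were not tested. Reads of 21-nt tRNA differed on MS-N from MS by -1249 rpm in Col-0 and 1219 in dcl4-2, and between dcl4-2 and Col-0 by -657 on MS and 1811 on MS-N. For 22-nt tRNA the same 4 differences were -2091, 549, -919 and 1721, and for 21-nt intergenic reads -5005, 11520.4, -6424 and 10102. Reads of 22-nt rRNA differed by medium by -553 in Col-0 and 592 in dcl4-2. By genotype 21-nt reads of the 5′ UTR differed by -89.9 on MS and 145 on MS-N, those of the 3′ UTR by -253 and 234, and 22-nt reads of the 5′ UTR by -113 and 236. The 22-nt share of exon reads differed by medium by -4.12 points in Col-0 and 2.36 in dcl4-2, and that of intergenic reads by genotype by 15.8 on MS and -4.61 on MS-N. Groups of 3 libraries were not tested for single values far from the rest.

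Reads of the 20 photosynthesis genes were low on MS-N in both genotypes and at both lengths. Normalization is argued against, since the median log2 change at 22 nt in Col-0 was -5.11 when scaled to rpm. Less cutting by DCL4 is argued against, since all 20 genes fell in dcl4-2 too (median log2 -3.93 at 21 nt), and on MS their pooled 22-nt share moved by -0.129 points from Col-0 to dcl4-2, against 59.5 over the secondary siRNA sources. On MS-N it moved by 14.5 points and stood at 38.0% in Col-0 against 50.8% on MS, so whether the reads left there were cut by DCL4 or are fragments of messenger RNA stays open. Less messenger RNA or less leaf tissue on MS-N was not tested.

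Chloroplast genes kept more of their 22-nt reads on MS-N in dcl4-2 than in Col-0. Normalization is argued against by a median interaction of 1.39 on the log2 scale when scaled to rpm, and more fragments of every length by the 21-nt median of -0.17. The interaction of 22-nt tRNA reads was 1.01 and that of 22-nt rRNA reads 0.87 on the same scale. At 21 nt they were 1.26 and 0.72, so these RNAs moved at both lengths where chloroplast genes did not, and whether more fragments of abundant RNA account for part of the pattern stays open. A 22-nt activity of dcl4-2 on chloroplast RNA stays open and was not tested.

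Replicate 1 of dcl4-2 on MS stood apart from replicates 2 and 3, with 26469 22-nt intergenic rpm against 66132 and 57302, and 17992 21-nt reads of transposable elements against 10067 and 10354. A Col-0 sample under its label is argued against by 1297 21-nt tasiRNA rpm, where the lowest Col-0 library on MS had 23904. Depth is argued against by 6319663 reads, inside the range of the other libraries. A difference in growth or handling could lie behind it and was not tested.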

How the results depend on the processing

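The scaling to rpm, the block and left-out libraries for the class table, the pseudogene list and the shuffled residuals were chosen after seeing the data, and the other alternatives before. Of 130 values of the main results under single alternatives 87 stayed within a tolerance and 43 did not. For counts of loci, classes and lists the tolerance was 1.5-fold of the total called, whatever the balance of rises and falls. For totals and shares it was the same sign and a change in effect under 1 SD. Correlations across genes had no tolerance and all stand among the 43. Of 630 calls at named loci 333 held under every alternative run, 297 were lost under at least 1, and 5 also changed sign. With a pseudocount of 0.1 the counts were 700 at 21 nt for medium in Col-0, 447 at 21 nt and 795 at 22 nt for genotype on MS-N, 183 at 22 nt for genotype on MS, and 7 and 136 for the interaction. The 21-nt interaction gave 228 with a pseudocount of 5, 29 without a filter, 297 with a minimum of 5, 30 with trimmed-mean scaling and 148 in rpm. With microRNA reads scaled to a common sum the counts were 2006 for medium in Col-0 at 21 nt, 1787 and 899 for genotype on MS at 21 and 22 nt, and 1688 and 1963 for genotype on MS-N. This scaling moves the median of all loci by -0.20 (medium in Col-0, 22 nt) to -0.44 (genotype on MS, 21 nt) in the 4 contrasts of groups, scaling to rpm by -0.19 (genotype on MS, 21 nt) to 0.15 (medium in Col-0, 21 nt), and trimmed-mean scaling by at most -0.14 (interaction, 22 nt). Such a shift toward lower values adds falls by construction, and this scaling takes the microRNA sum as constant. Without a trend limma called 87 and 78 loci for genotype on MS, 375 and 339 on MS-N, and 0 and 2 for the interaction, where 2645 loci had an unadjusted p under 0.05 at 21 nt. With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, the counts were 699 and 1244 for medium in dcl4-2, 26 and 23 for genotype on MS, and 349 and 522 on MS-N.

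Without microRNA the ratio of total 21-nt reads was 1.18 for medium in Col-0 (with it 1.43), 1.41 in dcl4-2 (1.74), 0.560 for genotype on MS (0.919) and 0.667 on MS-N, where it reversed (1.12). That of 22-nt reads for genotype on MS-N was 1.11 (1.15). The difference in 22-nt share without microRNA was 2.08 points for medium in Col-0, reversed from -1.85, -3.79 in dcl4-2 (-7.51), 18.5 for genotype on MS (6.28) and 12.7 on MS-N (0.616). Without microRNA the medium effect on this share did not pass over both genotypes (exact two-sided permutation p = 0.575). With a replicate block 0 of 28 classes passed for genotype against 15, and 20 against 21 for medium. For genotype 11 of the 15 were at the smallest sign-flip p, 0.0312, too few for it to pass adjustment (adjusted p = 0.0795), and 4 had p of 0.0625 to 0.0938. With an estimated correlation 24 list calls at 21 nt remained of 39 in number, and 27 of 39 at 22 nt. With a minimum of 5 the correlation of effects across genes was 0.253 at 21 nt and 0.114 at 22 nt for genotype, and 0.594 and 0.541 for medium. Calls that changed sign, all with microRNA reads scaled to a common sum, were MIR396a at 21 nt for medium in dcl4-2 (log2 -0.19) and genotype on MS-N (-0.24), MIR162b 22-nt, medium effect in dcl4-2 (-0.069), and at 22 nt MIR166a (-0.033) and MIR161 (-0.18) for genotype on MS-N.

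Leaving out 1 library gave, at 21 nt, 774 to 861 loci for medium in Col-0, 1833 to 2244 for medium in dcl4-2, 176 to 259 and 422 to 649 for genotype on MS and MS-N, and 1 to 211 for the interaction, and at 22 nt 863 to 959, 2331 to 2700, 203 to 318, 532 to 901 and 169 to 529 in the same order. At 21 nt the count of 893 for genotype on MS-N moved by more than 1.5-fold without Col-0 on MS-N library 1 (422), library 2 (422), library 3 (443), dcl4-2 on MS-N library 2 (587), library 3 (507). At 21 nt the count of 86 for the interaction moved by more than 1.5-fold without Col-0 on MS library 1 (41), library 2 (19), library 3 (1), Col-0 on MS-N library 1 (7), library 2 (20), library 3 (25), dcl4-2 on MS library 3 (211), dcl4-2 on MS-N library 1 (37), library 2 (32), library 3 (14). At 22 nt the count of 1273 for genotype on MS-N moved by more than 1.5-fold without Col-0 on MS-N library 1 (645), library 2 (532), library 3 (728), dcl4-2 on MS-N library 2 (786). At 22 nt the count of 412 for the interaction moved by more than 1.5-fold without Col-0 on MS library 2 (169), library 3 (192), Col-0 on MS-N library 1 (198), library 2 (178), library 3 (264), dcl4-2 on MS-N library 2 (210), library 3 (190). Ratios of total 21-nt reads ran from 1.39 to 1.5, 1.68 to 1.80, 0.888 to 0.959 and 1.09 to 1.14 for medium in Col-0, medium in dcl4-2, genotype on MS and genotype on MS-N, those of 22-nt reads from 1.27 to 1.36, 1.15 to 1.33, 1.13 to 1.31 and 1.14 to 1.16, and the differences in 22-nt share from -2.17 to -1.48, -10.3 to -5.95, 4.72 to 9.08 and 0.244 to 0.934 points. Class counts ran from 20 to 21 for medium and 11 to 16 for genotype. The cause was not tested where none is named. Not run were a quasi-likelihood count test, since the deposited means are not whole multiples of 1 step, a replicate block at loci, for want of replicate numbers, totals without the 10 highest loci, for want of their library values, and a block for gene lists. At 3 libraries a group a 2-fold change passed in 22 of 67 simulated loci at 21 nt. Under the single spread of that simulation most changes of that size would be missed.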

Other observations

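Annotated pseudogenes, a list added after the data were seen, lost reads on MS-N in dcl4-2. The list follows the RefSeq biotype and is not the pseudogene class. In Col-0 on MS it held 178400 recovered 22-nt reads over 3 libraries, where the class held 4138, 4500 and 4309. Whether the list holds genes of transposons was not checked. Of 3942 measured at 21 nt 27 rose and 367 fell (22 and 325 adjusted over the list alone), and of 4115 at 22 nt 61 rose and 638 fell (65 and 660 adjusted over the list alone), by limma with Benjamini-Hochberg. Between genotypes on MS-N 11 rose and 135 fell at 21 nt, and 35 rose and 213 fell at 22 nt. On MS 35 rose and 14 fell at 21 nt and 99 rose and 24 fell at 22 nt, and the median turned from 0.15 to -0.30 at 22 nt with microRNA reads scaled to a common sum and to -0.03 with scaling to rpm. In Col-0 44 rose and 56 fell on MS-N at 21 nt and 83 rose and 164 fell at 22 nt, while the median log2 change was 0.22 and 0.21, and it turned to -0.23 and -0.13 with microRNA reads scaled to a common sum.

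Among single loci, AT3G43828, annotated as a pseudogene, rose on MS-N in Col-0 from 99.9 ± 43.1 to 947 ± 66.6 normalized reads at 21 nt (9.49-fold) and in dcl4-2 from 299.6 ± 291 to 2296 ± 366 (7.67-fold). BXL1, a xylosidase of the cell wall, and BGAL1, a galactosidase, fell in Col-0 96.3-fold and 65.9-fold at 21 nt. STP1, a sugar transporter, fell 89.9-fold at 22 nt in Col-0, and DOX1, an enzyme of fatty acid oxidation, rose 28.6-fold at 22 nt in dcl4-2. AT5G43730 and AT5G43740, a pair of disease resistance genes, held 21.2 ± 2.82 and 92.5 ± 12.4 reads of 22 nt in Col-0 and 190.0 ± 33.2 and 561 ± 83.1 in dcl4-2 on MS. AT3G62200 rose at 22 nt from 0.293 ± 0.507 to 43.3 ± 16.2 in dcl4-2 on MS.

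The tests in this paragraph were chosen after the result was seen. A hypothesis is that a gain in 22-nt share in dcl4-2 marks loci of secondary siRNA. At the pooled sources this gain came from the loss of 21-nt reads. Their raw 22-nt reads, not scaled for depth, also went down, from 10941 to 4612 on MS and from 14846 to 4696 on MS-N. Single sources went both ways at 22 nt, with 7 higher and 12 lower on MS and 11 and 11 on MS-N in limma. Their median log2 change was 0.34 on MS and 0.94 on MS-N. The median rise of the 22-nt share on MS-N was 54.1 points over the listed sources with at least 50 reads in every group, with quartiles of 49.6 and 63.6. Over microRNA genes it was 0.251 points, with quartiles of -1.46 and 1.17, which argues against a turn of every 21-nt read into 22 nt whatever its source. DCL1 makes microRNAs, so they cannot show what became of 21-nt reads that DCL4 makes. The gain was not confined to secondary siRNA, since over 66 chloroplast genes it was 31.1 points on MS-N, with quartiles of 19.9 and 38.6, and 4.59 on MS, and over mitochondrial genes 12 points on MS-N. For the 22-nt reads at the listed sources in dcl4-2 another dicer, such as DCL2, is a candidate explanation from background knowledge, and no group of this study lacks it.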
